A study of Mus musculus with 14 samples.

How the data were processed

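H3K4me3 PLAC-seq had been done in 14 samples of F123 mouse cells, of which the 8 samples of 4 groups were analysed: ESC control (auxin for 0 h), ESC auxin (48 h), NPC control and NPC auxin (both day 4), with 2 samples per group according to the sample titles. Per the labels' protocols, CTCF was depleted by adding 1 µl of 500 mM auxin per ml of medium, and the assay followed the publications on PLAC-seq and MAPS. The submitters' processing notes name BWA, Picard and the build mm10, with no versions. The analysis started from 8 deposited lists, 1 per group and caller. That a list belongs to MAPS or FitHiChIP is per the labels, and whether the 2 samples of a group were pooled before calling is not given in the sources used here. The 6 samples of the 3 groups with dCas9 were not analysed here.

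Per the file headers, each MAPS line holds a pair of 10 kb bins with a read count, the background expected by the caller, the ratio of the count to that background, an FDR, and for each anchor whether it holds an H3K4me3 peak. In every deposited MAPS list the count was at least 12, the ratio at least 2.00 and the FDR under 0.01, the distance ran from 20 to 1000 kb, and 19 autosomes were present. The deposited FitHiChIP lists give a contact count per bin pair, the reads covering each anchor, a q-value, always under 0.01, and the fraction of all contacts expected in the bin pair under the caller's model, over 20 to 2000 kb and 21 chromosomes including X and Y. The expected contacts divided by that deposited fraction gave the same whole number on every line of a list, which was taken as its total number of contacts. All counts, ratios, FDR values and q-values are the authors' own and were used to rank or filter loops within a list, apart from the contact counts compared at shared loops. In each list every loop had a peak bin at 1 or both anchors, so the lists hold no contacts between other regions, and a contact absent from a list may have fallen just short of a threshold. The control and auxin MAPS lists of a cell type marked 100% of their shared bins alike (17775 in ESCs, 26469 in NPCs). The peak classes therefore do not show H3K4me3 after auxin. The MAPS control lists marked 93.0% of 31070 shared bins alike, so some pairs may have been open to calling in only 1 cell type.

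The MAPS lists were the main ones, since the labels cite that method, and the FitHiChIP lists gave the alternative caller. A loop was shared when both anchors lay in the same bins in both lists. Shares carry exact Clopper-Pearson 95% intervals, and values per chromosome were given as a description. Distance was counted from anchor start to anchor start, in classes of under 100 kb, 100 to 200 kb, 200 to 500 kb and 500 kb to 1 Mb. Gaps within classes, in the closing section, used 10 classes of FDR and 4 of distance. Contact counts at shared loops were compared as log2 ratios centred on the median of all shared loops. The 3 comparisons were ESC auxin against ESC control, NPC auxin against NPC control, and NPC control against ESC control. With 1 list per group no test of the conditions was possible and no p-value is given.

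Gene positions came from a RefSeq table of the assembly GRCm38.p6, whose chromosomes are those of mm10. It gives no strand, so the transcription start sites that had been planned as promoter positions could not be used. The promoter bin of a protein-coding gene was taken instead as the 10 kb bin of a gene end that any deposited list marks as an H3K4me3 peak bin. Of 21887 genes, 9018 had 1 marked end, 1898 had both ends in 1 marked bin, 3630 had both ends marked in different bins and 7341 had none, which left 14546 genes in 11953 bins. For genes with both ends marked, the end with more reads was used, and such bins were left out of the ranked bins. The marked bin can be the promoter of a neighbouring or antisense gene, and a bin shared by several genes counts for each of them.

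Loops per promoter bin were compared as log2 of the loops plus a pseudocount of 1 in one list over the other, minus the log2 ratio of the list totals, so that a bin that changed as its list did lies near 0. The pseudocount moves such a bin above 0 where the second list is the shorter one, and more so the fewer its loops. The intervals carry no pseudocount, and the random lists, matched on loops, carry the same shift as the lists placed among them. Exact binomial intervals for this change came from the share of a bin's loops in the second list. They treat loops as independent, although many are adjacent pairs (the 56714 MAPS loops of ESC control formed 22808 clusters), so they are likely too narrow. Ranked bins were chosen as extremes, so intervals that exclude 0 there follow in part from that choice. The named bins were, per comparison, the 10 lowest and 10 highest by this change among bins with at least 10 loops over the lists and a change of the same sign in the FitHiChIP lists, with at most 3 symbols per bin. Of each gene list the 2 lowest and 2 highest members with at least 5 loops were named, and Vcan in every group. The results of some genes that met these rules are not reported. Further genes in the closing section were chosen after their values were seen. The gene lists were pluripotency, neural progenitor, clustered protocadherins, Hox, retinoic acid response, housekeeping, CTCF and cohesin, and the markers of other cell types mesoderm and endoderm, neural crest and neuron. A list's median change was placed among 10000 random lists of the same size, matched on the mean number of loops (seed 7). Of 10 quantile bins set for the matching, ties left 8 in the ESC comparison and 9 in the others. Percentiles under 2.5 or over 97.5 were called outside the central 95%. These percentiles describe the lists and test no condition. The random lists were drawn without regard to position, while the clustered protocadherins (57 genes in 40 bins) and Hox genes (39 in 30) share or neighbour bins. Their percentiles can therefore be too extreme. Each comparison has 10 such lists, of which 2 lay outside in ESCs, 1 in NPCs and 2 between the control lists.

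The list step was tested on simulated data with 100 lists of 20 genes and 1000 random lists each. With no change, 2% of lists fell outside for the ESC comparison (10719 genes), 3% for the NPC comparison (11962 genes) and 7% between control lists (12151 genes). These lists were drawn from the same genes as the random lists, with loops redrawn independently, so low shares follow by construction. Shorter lists and lists of genes that share or neighbour bins were not checked in this way. With 75% of the loops of the second list moved to the first list, 99%, 100% and 100% of lists were found below. This contrast is larger than a loss of the same loops, so it does not give the detection of such a loss. The alternatives tried were other tolerances for a shared loop (1 or 2 bins), the FitHiChIP lists, pairs in both callers, the stronger part of each list, lists cut to equal length by FDR, merged adjacent pairs, autosomes only, neighbouring bins, all annotated genes, a pseudocount of 5, at least 5 loops per gene, means in place of medians and other scalings of contact counts. Added after seeing the data were an FDR under 1e-06, FitHiChIP lists without crowded windows, each bin counted once, bins with ambiguous ends left out, total contacts as a scaling, and the alternatives for the gap between H3K4me3 classes. A crowded window was a 1 Mb window with at least 100 FitHiChIP loops and at least 5 times as many as MAPS in both control lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.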

Results

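The series profiled chromatin contacts of active promoters in mouse cells by H3K4me3 PLAC-seq, a proximity ligation assay in which fragments carrying the promoter mark trimethylated histone H3 lysine 4 are immunoprecipitated before sequencing. The cells were F123 embryonic stem cells (ESCs) whose CTCF protein carries an auxin-inducible degron, so that auxin removes CTCF, and neural precursor cells (NPCs) derived from them and collected on day 4 of differentiation. Of the 14 samples in 7 groups, 8 samples belong to the 4 groups analysed here, with 2 samples in each: ESCs without auxin, ESCs after 48 h of auxin, NPCs without auxin and NPCs differentiated with auxin. The other 3 groups, NPCs with dCas9 alone or with dCas9 fused to CTCF at the Vcan locus, were not analysed here. Each of the 4 groups was represented by 1 list of called contacts (loops, pairs of 10 kb bins) from each of the callers MAPS and FitHiChIP, so no difference between groups has a replicate check, and the 95% intervals cover counting error only. The total number of contacts behind each FitHiChIP list was 47519917 in ESC control, 48307867 in ESC auxin, 52337421 in NPC control and 59961568 in NPC auxin. MAPS called 56714, 27610, 82861 and 41667 loops in the same order, and FitHiChIP called 33475, 22705, 44892 and 24836. A bin with 0 loops had no contact past the callers' thresholds, which does not mean that it made none.

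**Figure D1:**
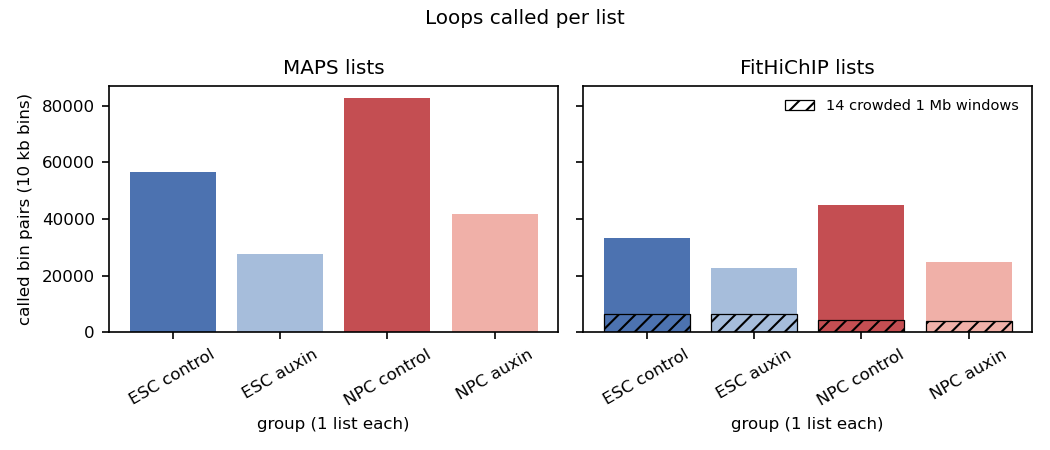
Number of called loops (pairs of 10 kb bins) in the MAPS lists (left) and the FitHiChIP lists (right) of the 4 groups, 1 list per bar, so there are no error bars. The hatched part of the FitHiChIP bars counts loops in 14 crowded windows of 1 Mb, which held 6487 of the 33475 loops in ESC control and 64 of the 56714 MAPS loops.

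Vcan, which encodes the extracellular matrix proteoglycan versican, is the locus that the study targeted with dCas9. It lies on chromosome 13 at 89655309 to 89743027 (mm10), and the H3K4me3 peak bin at its end covers 89740001 to 89750000. This bin held 6 MAPS loops in ESC control and 0 in ESC auxin, and 14 in NPC control and 0 in NPC auxin. FitHiChIP called 8, 0, 18 and 1 loops there. In ESC control the MAPS partners spanned 90030001 to 90150000, over the DNA repair gene Xrcc4 and its neighbour Tmem167, with 26 contacts at the strongest one. In NPC control the partners reached from 90010001 to 90750000, up to 1000 kb away. The FitHiChIP contact of Vcan with the bin of Atp6ap1l at 90880001, 1140 kb away, had 36 contacts in NPC control and 17 in NPC auxin, where it was the loop that remained. Relative to the ratio of the list totals, the log2 change at Vcan was -1.77 in ESCs, with an upper interval bound of 0.80 that does not exclude 0, and -2.92 in NPCs, with an upper bound of -0.74. Reads covering the Vcan bin were 6801 in NPC control and 6748 in NPC auxin, and 4227 in ESC control.

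**Figure D2:**
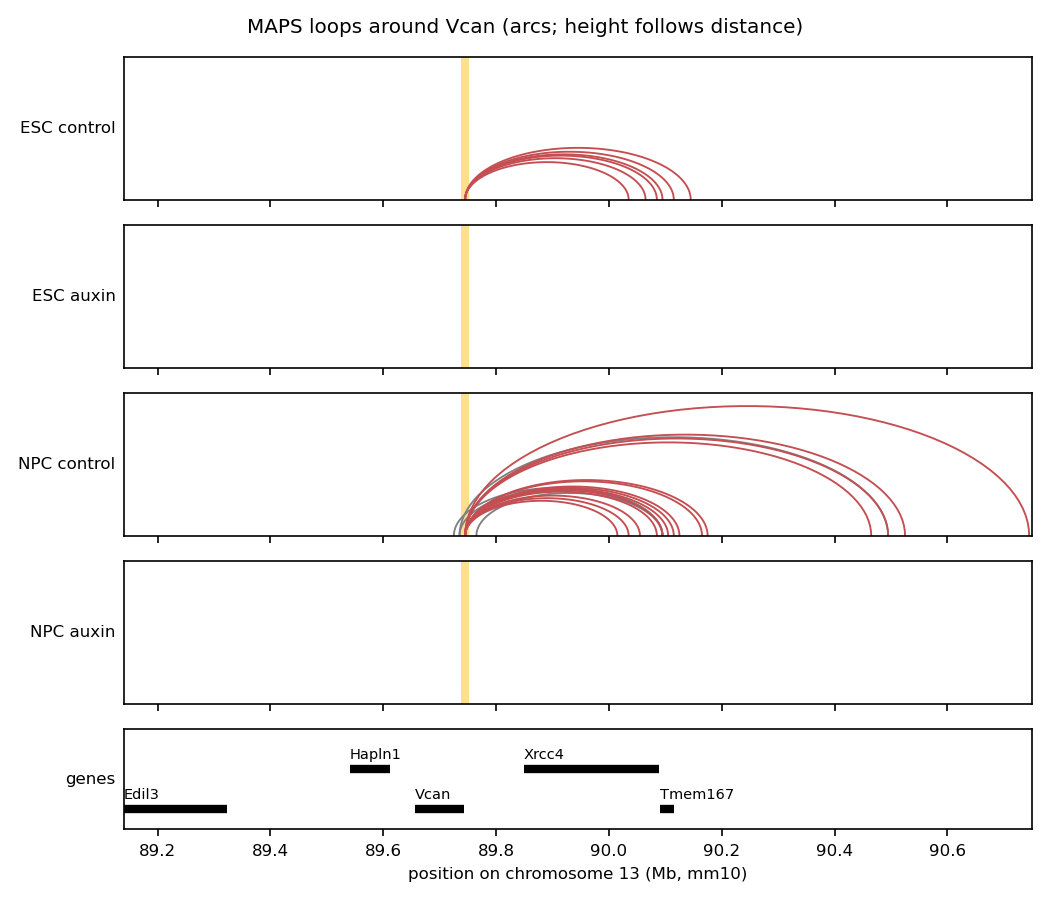
MAPS loops around Vcan on chromosome 13 (x axis, position in Mb, mm10) in the 4 groups. Red arcs end in the Vcan bin (yellow), grey arcs end elsewhere, and arc height follows distance: 6 loops in ESC control, 18 in NPC control of which 14 end at Vcan, and 0 in both auxin lists.

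The comparison of ESCs with and without auxin asks which promoter contacts are called without CTCF, the zinc finger protein that marks domain boundaries and loop anchors. The promoter bin of Tgfb3, a TGF-beta family ligand, held 26 loops in control and 0 after auxin (chromosome 12, 86070001 to 86080000). The bins of Cemip, which acts in hyaluronan breakdown, and of the kinase gene Nuak1 each held 17 and 0, and that of Fst, the activin antagonist follistatin, held 15 and 0. In the opposite direction, Gata6, a transcription factor of endoderm, held 4 loops in control and 15 after auxin (chromosome 18, 11050001 to 11060000). Pwp1 held 0 and 11, with partners at a median distance of 650 kb.

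Among the 964 promoter bins that qualified for ranking, the 10 with the lowest relative change each held 13 to 26 loops in ESC control and 0 after auxin. Besides the genes above they were Abtb2 with 16 control loops, Dnpep and Stox2 with 14 each, and Adcy3, an adenylyl cyclase, Alg10b, a glucosyltransferase of N-glycan synthesis, and Nedd4l, an E3 ubiquitin ligase, with 13 each. The upper bounds of their intervals, given for bins chosen as the lowest, ranged from -1.68 for Tgfb3 to -0.57 for Nedd4l. FitHiChIP called 5 and 2 loops at Nuak1 and at Fst, 5 and 1 at Stox2 and 3 and 1 at Nedd4l, and 0 after auxin at the others. Where both FitHiChIP lists gave reads for a bin, these were 3224 and 3138 at Nuak1, 3826 and 3992 at Fst, 6884 and 6766 at Stox2, and 4613 and 5270 at Nedd4l. The 10 bins with the highest change also included the shared bin of Arpc5l and the ribosomal protein gene Rpl35 (1 and 11 loops), Slc37a1 (2 and 11), Gprc5c and Thumpd3 (4 and 16 each), Atp1b2, a subunit of the sodium pump (3 and 11), Rimbp2 (2 and 8), and the genes 2610044O15Rik8 (1 and 9) and Rslcan18 (2 and 9). Reads were higher after auxin at some of these bins, with 5795 and 7387 at Gata6, 3834 and 4788 at 2610044O15Rik8 and 4665 and 5769 at Rslcan18, and lower at others, with 10769 and 10481 at Slc37a1 and 5515 and 5191 at Atp1b2. Gata6 had 3 and 8 FitHiChIP loops, and its log2 change of 2.72 had an interval of 1.30 to 4.99. FitHiChIP called 1 and 1 loops at Slc37a1 and 3 and 3 at Atp1b2, so their change in that caller was higher only relative to the shorter auxin list.

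**Figure D3:**
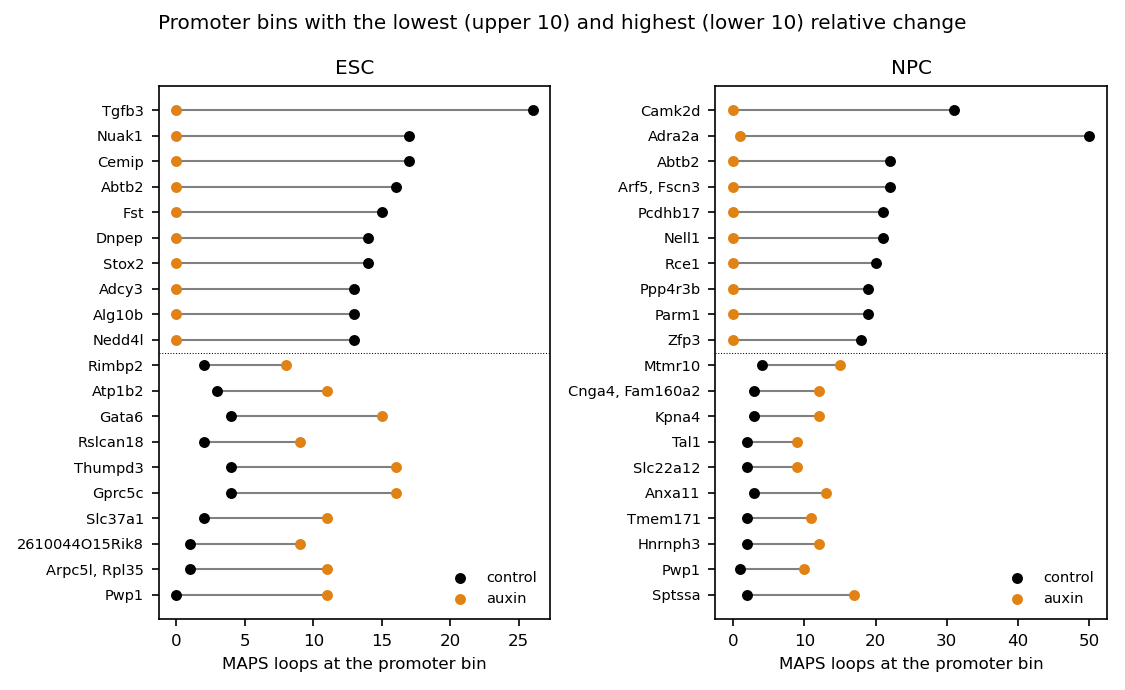
MAPS loops at the 20 ranked promoter bins of ESCs (left) and of NPCs (right), with control in black and auxin in orange (x axis, loops per bin, 1 list per point). The upper 10 bins have the lowest change relative to the list totals, led by Tgfb3 (26 and 0) and Camk2d (31 and 0), and the lower 10 have the highest.

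Of the 10 gene lists, the retinoic acid response genes stood lowest in ESCs, by median and by percentile: their 5 genes with loops held 66 loops in control and 20 after auxin, and the median change of -1.77 lay at percentile 0.035 of 10000 random lists matched on loops. The pseudocount raises the medians of both auxin comparisons, so the lists are placed by their percentiles. Stra8, which acts at entry into meiosis, held 12 and 0, and Dhrs3, a retinaldehyde reductase, held 28 and 3, while Cyp26a1, which degrades retinoic acid, held 18 and 14, and Cyp26b1 2 and 3. The clustered protocadherins, cell surface proteins of neurons, stood highest by percentile (99.99), with a median of 0.87 that 4 other lists exceeded. They held 268 loops in control and 232 after auxin over 57 genes in 40 bins, 32 genes having fewer loops and 19 more. Pcdhb5 held 5 and 12 and Pcdha4 6 and 13, against 13 and 2 at the bin of Pcdhb19 and Pcdhb20. In the FitHiChIP lists neither list lay outside the central 95%, with percentiles of 73.2 for the clustered protocadherins and 6.24 for the retinoic acid response genes. With neighbouring bins counted, the retinoic acid response genes lay at percentile 15.8.

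The remaining lists lay inside the central 95% of random lists in ESCs. The pluripotency genes had a median of 0.98 (percentile 95.8, or 28.6 in the FitHiChIP lists), with 55 and 49 loops over 16 genes. The neural progenitor genes had a median of 0.30 (percentile 41.3), and 17 of their 19 genes held fewer loops after auxin, while Pou3f2 and Ncam1 each held 3 and 8. The Hox genes, which pattern the body axis, had a median of 0.20 (percentile 11.5, or 91.7 in the FitHiChIP lists). Hoxd13 held 22 and 0 loops and Hoxa13 26 and 1, whereas Hoxb7 held 26 and 24 and Hoxb2 5 and 7. Medians were 0.45 (percentile 60.6) for mesoderm and endoderm genes, where Eomes held 10 and 1, Foxa2 18 and 11 and Mesp1 11 and 14, and 1.00 (percentile 89.0, or 39.0 among genes with at least 5 loops) for neural crest genes, of which 3 held more loops and 3 fewer: Snai2 7 and 0, Tfap2a 12 and 6 and Pax3 10 and 6. They were 1.04 (percentile 88.4) for neuron genes, with Rbfox3 at 2 and 7, and -0.28 (percentile 11.8, or 65.6 in the FitHiChIP lists) for genes of CTCF and cohesin, with Wapl at 4 and 1, Pds5b at 3 and 2 and Smc3 at 5 and 5. The housekeeping genes had a median of 1.62 (percentile 96.6), with Polr2a at 4 and 4 and Ppia at 1 and 6, and lay above the central range with neighbouring bins counted (99.1) or as a mean (99.9), but at percentile 47.1 in the FitHiChIP lists. Ppia went the other way in the FitHiChIP lists, with 5 and 2 loops. Klf4 held 4 and 2, Tbx3 15 and 10, Utf1 2 and 4 and Dppa5a 2 and 3.

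Over the whole list, ESC auxin held 48.7% as many MAPS loops as ESC control, and the number was lower on 19 of 19 autosomes, with ratios of 0.382 to 0.623 over the chromosomes. Of the 56714 control loops, 12979 were called again after auxin, which is 22.9% (95% exact interval 22.5 to 23.2), and 47.0% of the auxin loops were in the control list. The share called again was 45.8% in the strongest of 5 classes by FDR and 11.6% in the weakest. Pairs with an H3K4me3 peak bin at both anchors were called again in 32.7% of cases and pairs with a peak bin at 1 anchor in 19.4%, a gap of 13.4 percentage points. Peak bins at both anchors made up 26.4% of control loops and 36.2% of auxin loops, and promoter bins of protein-coding genes lay at both anchors of 7.38% and 11.3%. Of 1959 promoter bins with at least 10 loops over the lists, 1488 held fewer loops after auxin, 339 more and 55 none.

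The median distance between anchors was 230 kb in ESC control and 240 kb after auxin. At loops called in both lists the median log2 ratio of unscaled contact counts was -0.11 (quartiles -0.38 and 0.12, or -0.13 scaled by total contacts), and pairs from 500 kb to 1 Mb differed from all shared pairs by 0.03 (0.01 to 0.11). In the FitHiChIP lists this median was 0 (-0.02 scaled by total contacts), so that caller showed little of the lower counts. Pairs that fell below a threshold after auxin are not among the shared loops, so larger drops are not seen here. The share called again was 46.1% when anchors could differ by 1 bin and 43.3% in the FitHiChIP lists, where the gap between the H3K4me3 classes turned to -7.87 points and the difference in median distance was 130 kb in place of 10 kb. Outside 14 crowded windows, chosen after seeing the data, the FitHiChIP gap was 9.70 points and the distance difference 40 kb; the difference in promoter bins at both anchors, 3.90 points in MAPS, was 1.80 points in the full FitHiChIP lists and 7.35 points with neighbouring bins counted.

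The comparison of NPCs differentiated with and without auxin asks which promoter contacts are called on day 4 when differentiation ran with auxin. The sample titles give no hours of auxin for NPCs. A change of cell state with auxin cannot be told apart here from a direct loss of contacts. Camk2d, a calcium and calmodulin dependent kinase, held 31 loops at its promoter bin in control and 0 with auxin (chromosome 3, 126590001 to 126600000), and Adra2a, an adrenergic receptor, held 50 and 1 (chromosome 19, 54040001 to 54050000). Cdh2, the gene of N-cadherin, the main cadherin of the neural tube, held 17 and 0 (chromosome 18, 16800001 to 16810000). Sptssa, a subunit of the enzyme that starts sphingolipid synthesis, held 2 and 17 (chromosome 12, 54650001 to 54660000). Pwp1 again held more loops with auxin, 1 and 10, at a median distance of 645 kb.

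The 10 lowest of 1775 ranked bins each held 18 to 50 loops in NPC control and 0 or 1 with auxin. Beside Camk2d and Adra2a they were Abtb2 and the shared bin of Arf5 and Fscn3 with 22 control loops each, the protocadherin gene Pcdhb17 and Nell1 with 21 each, Rce1, a protease of prenylated proteins, with 20, Ppp4r3b and Parm1 with 19 each, and Zfp3 with 18. The upper interval bounds ran from -2.11 for Adra2a to -1.14 for Zfp3. In the FitHiChIP lists Camk2d held 10 and 1 loops, Abtb2 11 and 1, Rce1 16 and 4, Adra2a 43 and 19, and Zfp3 7 and 3. Relative to the list totals the FitHiChIP change was -1.61 at Camk2d, but only -0.28 at Adra2a and -0.15 at Zfp3. The near-complete loss at Adra2a and Zfp3 was thus seen in MAPS only. Reads, not scaled by total contacts, were 9769 and 9156 for Camk2d, 11097 and 12153 for Adra2a, 8310 and 8503 for Abtb2 and 9588 and 9425 for Rce1. The highest 10 further held the RNA binding protein gene Hnrnph3 (2 and 12 loops), Tmem171 (2 and 11), Anxa11 (3 and 13), the urate transporter gene Slc22a12 (2 and 9), Tal1, a transcription factor of blood formation (2 and 9), the importin gene Kpna4 (3 and 12), the shared bin of Cnga4 and Fam160a2 (3 and 12) and Mtmr10 (4 and 15). Unscaled reads there were 8704 and 9333 at Sptssa, 9110 and 10259 at Anxa11, 7287 and 7184 at Pwp1 and 10898 and 10196 at Kpna4. Hnrnph3 held 4 and 4 FitHiChIP loops, so its change in that caller was higher only relative to the shorter auxin list.

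The neural progenitor genes stood lowest of the 10 lists in NPCs by percentile (0.53 of the random lists), with a median change of -0.34. Their 20 genes with loops held 395 loops in control and 152 with auxin, and 19 of them held fewer with auxin and 0 more. Besides Cdh2 and Vcan, the list held at its upper end Ncam1 with 7 and 7 loops and Fgf15 with 19 and 17. The list lay at percentile 3.14 in the FitHiChIP lists and at 4.68 among genes with at least 5 loops, inside the central 95% in both cases. The neural crest genes had the lowest median, -0.51 (percentile 2.84), with Snai2 at 24 and 6 loops, Tfap2a at 37 and 11, Pax3 at 11 and 7 and Foxd3 at 16 and 18. The clustered protocadherins had a median of -0.01 (percentile 7.12), 49 of 57 genes holding fewer loops. Pcdhb16 and Pcdhb17 share a bin with 21 and 0 loops, Pcdhb8 held 2 and 6 and Pcdha7 2 and 3. That list lay below the central range in the FitHiChIP lists (0.345), with neighbouring bins (0.015) and as a mean (0.00).

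The Hox genes had a median of 0.22 (percentile 12.6) in NPCs, with 823 and 465 loops over 39 genes, and lay at percentile 0.58 in the FitHiChIP lists. Hoxd13 held 47 and 9 loops and Hoxa13 39 and 7, while Hoxb1 held 14 and 18 and Hoxc8 11 and 14. The retinoic acid response genes had a median of -0.30 (percentile 6.39, or 54.9 in the FitHiChIP lists), with Stra8 at 18 and 5, Cyp26b1 at 11 and 3, Dhrs3 at 33 and 19 and Cyp26a1 at 23 and 23. Pluripotency genes had a median of 0.67 (percentile 87.1): Klf4 held 26 and 5, Tbx3 64 and 29, Sall4 8 and 16 and Utf1 2 and 4. Mesoderm and endoderm genes had a median of 0.19 (percentile 37.7), with Gsc at 10 and 0, Mesp1 at 15 and 6, Sox17 at 21 and 21 and Foxa2 at 26 and 25. The FitHiChIP lists gave Gsc 2 and 2 loops, which turns its relative change to 0.85. Medians were -0.01 (percentile 37.1) for neuron genes, 0.18 (percentile 61.1) for housekeeping genes, with Polr2a at 4 and 1, Tbp at 6 and 3 and Eef1a1 at 4 and 7, and -0.01 (percentile 33.3) for genes of CTCF and cohesin, with Rad21 at 5 and 0, Pds5b at 7 and 2, Smc3 at 10 and 7 and Wapl at 5 and 4.

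**Figure D4:**
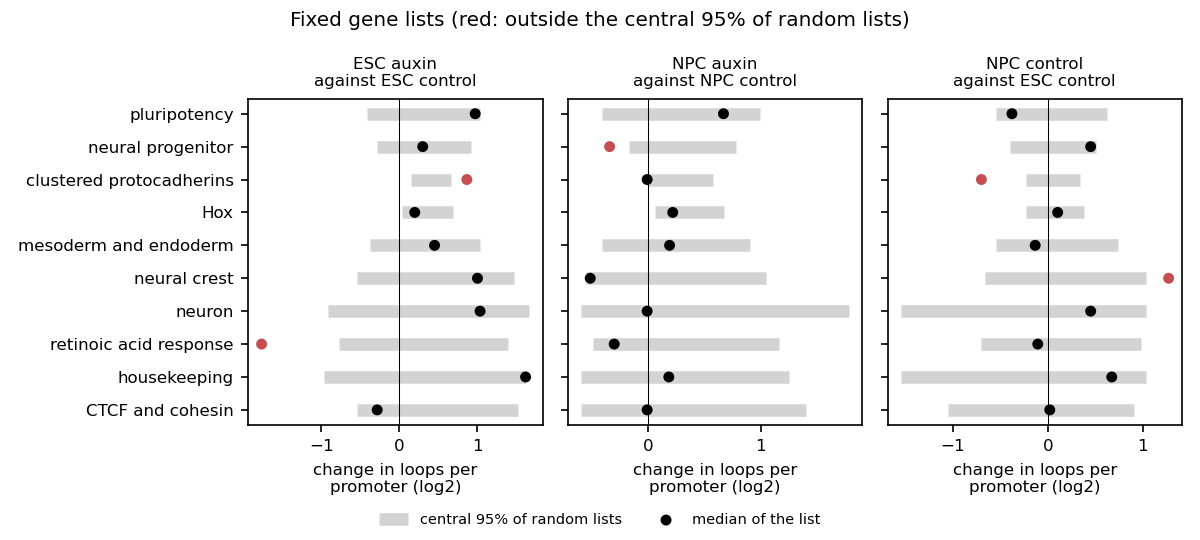
Median change in loops per promoter bin (x axis, log2, relative to the ratio of the list totals) of the 10 gene lists in the 3 comparisons, with the central 95% of 10000 random lists matched on loops in grey. Red points lie outside it: retinoic acid response (-1.77) and clustered protocadherins (0.87) in ESCs (neither outside in the FitHiChIP lists), neural progenitor (-0.34) in NPCs (inside in the FitHiChIP lists), and clustered protocadherins (-0.70) and neural crest (1.27) between the control lists.

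NPC auxin held 50.3% as many MAPS loops as NPC control, lower on 19 of 19 autosomes, with ratios of 0.392 to 0.638 over the chromosomes. Of the 82861 control loops, 22391 were called again with auxin, or 27.0% (26.7 to 27.3), and this share was 52.0% in the strongest and 14.3% in the weakest of 5 FDR classes. Loops with an H3K4me3 peak bin at both anchors were called again in 39.1% of cases and those with 1 in 24.2%, a gap of 14.9 points. In the class with both, the share was 25.9% under 100 kb and 48.2% from 500 kb to 1 Mb. Peak bins lay at both anchors of 19.1% of control loops and 26.6% of auxin loops, and promoter bins at both anchors of 6.73% and 9.79%. Of 3282 promoter bins with at least 10 loops, 2590 held fewer loops with auxin, 520 more and 93 none. The median distance was 260 kb in control and 300 kb with auxin, a difference of 40 kb against 13.3 kb (SD over chromosomes). At shared loops the median log2 ratio of unscaled contact counts was -0.07 (quartiles -0.38 and 0.19), or -0.27 scaled by total contacts, and pairs from 500 kb to 1 Mb differed from all shared pairs by -0.01 (-0.03 to 0.00). In the FitHiChIP lists the median was 0 unscaled and -0.20 scaled by total contacts. The ratio of list lengths was 0.311 at an FDR under 1e-06, the share called again was 50.03% within 1 bin, and the difference in median distance was 80 kb in the FitHiChIP lists. There the H3K4me3 gap was 25.4 points outside the crowded windows, and promoter bins at both anchors differed by 8.59 points in place of 3.06.

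**Figure D5:**
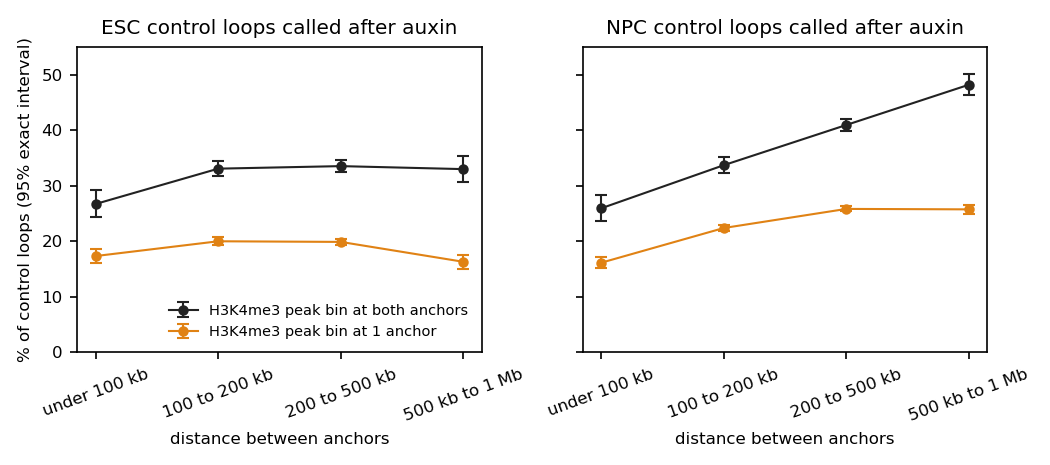
Share of control MAPS loops called again after auxin (y axis, percent, bars are 95% exact binomial intervals) by distance between anchors and by the number of anchors with an H3K4me3 peak bin, in ESCs (left) and NPCs (right). Pairs with peak bins at both anchors lie above the others in all 4 distance classes, at 25.9% to 48.2% in NPCs against 16.1% to 25.8%.

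The comparison of the control lists asks which promoter contacts differ between NPCs and ESCs with CTCF present. Erbb4, a neuregulin receptor, held 0 loops in ESCs and 37 in NPCs (chromosome 1, 69100001 to 69110000), and the insulin receptor substrate gene Irs2 held 0 and 36 (chromosome 8, 11000001 to 11010000). Gli3, a transcription factor of the Hedgehog pathway, held 0 and 30, and the Wnt receptor gene Fzd8 0 and 26. Among neural progenitor genes Sox11 held 0 and 47 and Cdh2 0 and 17. In the opposite direction, Tmem235 held 17 and 0 (chromosome 11, 117860001 to 117870000) and Rfx4, a transcription factor of brain development, held 15 and 2.

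The 10 highest of 1975 ranked bins each held 0 loops in ESC control and 26 to 37 in NPC control, and the lower interval bounds ran from 2.71 for Erbb4 to 2.17 for Fzd8. The others were Dach1 with 32 loops, Camk2d with 31, Erlin2 with 29, Twist1, a transcription factor of mesenchyme and neural crest, with 27, Satb1, a chromatin organiser, with 27, and the myosin phosphatase subunit gene Ppp1r12a with 26. Reads at several of these bins were also higher in NPCs, with 2460 and 10165 at Gli3, 3320 and 9769 at Camk2d, 4842 and 10398 at Erbb4 and 2704 and 9049 at Fzd8. Over all 11939 marked bins with reads in both lists the median log2 ratio was 0.39. Relative to that median the change was 0.71 at Erbb4, 1.16 at Camk2d, 1.35 at Fzd8 and 1.65 at Gli3. The lowest bins held 10 to 17 loops in ESC control and 0 to 3 in NPC control, among them Dab2ip 10 and 0, Thrsp 15 and 1, Cyp4f40 10 and 1, Adamtsl3 14 and 2, Wscd2 15 and 3, and Krt2, a keratin gene, and the exonuclease gene Isg20 11 and 2 each.

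The clustered protocadherins lay below every one of the 10000 random lists (percentile 0.00), with a median change of -0.70, and 31 of 57 genes held fewer loops in NPCs and 22 more. Since these genes share or neighbour bins and the random lists do not follow position, that percentile can be too extreme. Their loops numbered 268 in ESC control and 249 in NPC control, while the whole list had 146% as many. Pcdha3 held 6 and 1 and Pcdhac2 7 and 2, against 1 and 6 at Pcdhgc3 and 4 and 8 at Pcdhb1. The neural crest genes, markers of another cell type than the one named in the labels, had a median of 1.27 (percentile 99.1), and 6 of 6 genes held more loops in NPCs. Twist1 held 0 and 27, Foxd3 1 and 16, Tfap2a 12 and 37 and Pax3 10 and 11, and in the FitHiChIP lists Foxd3 held 2 and 3 loops, a relative change of -0.01. Neural progenitor genes had a median of 0.45 (percentile 94.7), 15 of 21 genes holding more loops, with Nes at 8 and 2 and Hes5 at 3 and 2. They lay above the central range with neighbouring bins (99.3) or as a mean (97.9).

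Pluripotency genes had a median of -0.38 (percentile 16.7), with 9 of 17 genes holding more loops in NPCs and 6 fewer. Their 55 loops in ESCs and 180 in NPCs include 15 and 64 at Tbx3 and 4 and 26 at Klf4. Part of the rise lies at Sox2, also a gene of neural progenitor cells, whose loops are given in the closing section. Klf5 held 0 and 10, whereas Prdm14 held 3 and 2 and Sall4 7 and 8. Among genes with at least 5 loops this list lay at percentile 99.6, but at 7.39 in the FitHiChIP lists and 5.91 with neighbouring bins. Hox genes had a median of 0.11 (percentile 64.5), with Hoxa2 at 1 and 12, and 17 and 15 at the bin of Hoxc4 and Hoxc5. They lay at percentile 98.9 in the FitHiChIP lists and at 99.8 with neighbouring bins. Medians were -0.13 (percentile 28.0) for mesoderm and endoderm genes, with Gata6 at 4 and 23, Sox7 at 0 and 6, Hand1 at 5 and 4 and Cdx2 at 27 and 25, and 0.45 (percentile 73.8) for neuron genes, with Elavl3 at 4 and 1. They were -0.10 (percentile 34.3, or 76.2 in the FitHiChIP lists) for retinoic acid response genes, with Rara at 6 and 2, Dhrs3 at 28 and 33, Cyp26b1 at 2 and 11 and Stra8 at 12 and 18. Housekeeping genes had a median of 0.68 (percentile 94.2, or 8.80 in the FitHiChIP lists), with Polr2a at 4 and 4 and Tbp at 2 and 6, and genes of CTCF and cohesin 0.02 (percentile 51.5), with Mau2 at 4 and 1, Wapl at 4 and 5, Rad21 at 1 and 5 and Pds5b at 3 and 7.

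Of the ESC control loops, 28547 were also called in NPC control, or 50.3% (49.9 to 50.7), and these made up 34.5% of the NPC control list. The NPC control list was longer on 19 of 19 autosomes, with a mean ratio of 1.52 ± 0.224 (SD over chromosomes). Total contacts in NPC control were 110% of those in ESC control, and reads at marked bins had a median log2 ratio of 0.39. The part of these in the longer list was not tested. The share was 76.6% in the strongest and 33.5% in the weakest FDR class of the ESC list. Loops from 500 kb to 1 Mb made up 8.74% of the ESC list and 16.2% of the NPC list, with median distances of 230 kb and 260 kb. Of 3491 promoter bins with at least 10 loops, 2567 held more loops in NPCs and 706 fewer. At shared loops the median log2 ratio of unscaled contact counts was 0.19 (quartiles -0.15 and 0.57), or 0.05 scaled by total contacts, and pairs from 500 kb to 1 Mb lay 0.18 (0.15 to 0.20) above all shared pairs. The share also called in NPCs was 82.3% within 2 bins, and the difference in promoter bins at both anchors, -0.65 points, was 2.29 points in the FitHiChIP lists.

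The callers shared part of their lists. Of the MAPS loops, FitHiChIP called 29.9% in ESC control, 28.9% in ESC auxin, 33.1% in NPC control and 25.6% in NPC auxin at exact bins, and 53.8%, 49.2%, 57.6% and 47.2% within 1 bin. Of the FitHiChIP loops, MAPS called 50.7%, 35.2%, 61.0% and 42.9% in the same order of lists. Ctcf itself held 0 MAPS loops in ESC control, 0 in ESC auxin, 1 in NPC control and 0 in NPC auxin, and the level of its protein was not measured in the lists.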

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

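Of the tests below, those of depth, of reads at the anchors, of the number of control lists and of dense true contacts were chosen after the results had been seen, and those of call strength, of the caller's background and of near-identical copies before their values were computed. The results of the next paragraph were picked out because they are a signal in parts of the FitHiChIP lists that the MAPS comparisons do not cover, above the 0 loops that MAPS has there.

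FitHiChIP called loops on chromosome X, which the MAPS lists leave out: 526 in ESC control, 340 in ESC auxin, 938 in NPC control and 540 in NPC auxin. At the X-linked gene Efnb1, an ephrin ligand, the promoter bin held 18, 4, 29 and 9 FitHiChIP loops in the same order. Flna, the gene of filamin A, held 8, 2, 9 and 3, Tmsb4x, the gene of thymosin beta 4, 7, 7, 21 and 10, and Bcorl1 8, 12, 8 and 8. On X, 32.5% of control loops were called again after auxin in ESCs (28.5 to 36.7) and 31.6% in NPCs (28.6 to 34.6). Beyond 1 Mb, the upper limit of MAPS, FitHiChIP called 5859 loops in ESC control, 5680 in ESC auxin, 6966 in NPC control and 5714 in NPC auxin, and 74.5% (ESCs) and 55.2% (NPCs) of the control loops there were called again after auxin. The loops beyond 1 Mb include the contact of Vcan with the bin of Atp6ap1l. The crowded windows weighed below, where 85.6% (ESCs) and 82.1% (NPCs) of control loops at all distances were called again, were not set apart here. The shares beyond 1 Mb thus do not show that long contacts held without CTCF.

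The first pattern weighed is the shorter MAPS lists after auxin. A lower depth would need fewer contacts after auxin, but the totals behind the FitHiChIP lists were 102% (ESCs) and 115% (NPCs) of those of control. In the MAPS lists, which give no total, the background expected by the caller at shared loops had a median log2 ratio of 0.03 in ESCs and 0.20 in NPCs, so neither caller's values show a lower depth after auxin. Loss of H3K4me3 reads at the anchors cannot be told apart from a loss of contacts here: the median centred log2 change in reads at promoter bins that kept under 50% of their loops was -0.0167 in ESCs and -0.0386 in NPCs, but reads were listed for only 65.4% and 74.6% of these bins. A difference between cultures or libraries unrelated to auxin cannot be told apart from loss of CTCF either, since each cell type has 1 MAPS control list. In NPCs a cell state changed by auxin during differentiation cannot be told apart from a direct loss of contacts, and was not tested.

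The second pattern is that pairs with an H3K4me3 peak bin at both anchors were called again more often after auxin. Differences between classes of FDR and distance do not account for all of it: within these classes the gap was 9.29 points in ESCs and 10.9 in NPCs, against 13.4 and 14.9 points before. Calls can still differ in strength within a class of FDR. If MAPS fits the background separately, FDR may also not be the same scale for both kinds of pair. The values therefore do not exclude stronger calls as a cause. Separate background fits of MAPS for the classes are not the sole cause, since FitHiChIP gave gaps of 9.70 and 25.4 points outside the crowded windows, which were chosen after seeing the data, although the full ESC lists of that caller gave -7.87 points. A biological explanation, promoter pairs that hold without CTCF, was left open by these values and was not tested further.

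The third pattern is the crowding of FitHiChIP loops in 14 windows of 1 Mb, which held 19.4%, 28.6%, 9.45% and 16.2% of the loops in ESC control, ESC auxin, NPC control and NPC auxin. In these windows 85.6% of control loops were called again in ESCs and 82.1% in NPCs, against 33.2% and 30.9% elsewhere. Reads shared between near-identical copies are consistent with a mean mappability of MAPS anchor bins that differed by -0.116 there (0.824 against 0.940, 150 bins inside). Dense true contacts would be seen by both callers, but the share of MAPS loops in the windows was at most 0.856% of the FitHiChIP share; the windows were chosen, after seeing the data, for few MAPS loops, so this value follows in part from the choice and does not rule such contacts out.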

How the results depend on the processing

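The settings named here were chosen before the data were examined, except an FDR under 1e-06, the lists without crowded windows, the authors' H3K4me3 peak bins at both anchors, bins with ambiguous ends left out, each bin counted once, scaling by total contacts, and all settings for the gap between H3K4me3 classes. No paired analysis was possible because each group has 1 list and no values per replicate, so a replicate block and leaving out each replicate were not run. The settings for convergent CTCF motifs were not run, since no genome sequence was used here. Of 126 alternatives for 31 results, 48 left the value within its spread (counts and ratios within 1.5 times), 74 moved it and 4 turned the sign of a value whose interval excludes 0, of which 2 are scalings common to all pairs. For the 162 values of named genes, the sign was kept in 148 with FitHiChIP (60 of them ranked bins selected for that sign, and 88 of the other 102), 149 with lists cut to equal length, 159 with neighbouring bins and 156 with a pseudocount of 5. For the values below the cause was not tested, apart from the wider tolerances, which admit more pairs by construction. Autosomes only removes nothing from MAPS, and keeping the stronger loops of each list fixes the ratio of list lengths by construction.

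The share called again after auxin in ESCs was 46.1% within 1 bin, 55.6% within 2 bins, 43.3% with FitHiChIP, 33.2% with FitHiChIP outside the crowded windows, 23.5% for pairs in both callers, 22.3% among the stronger loops of each list and 32.2% at equal length. In NPCs it was 50.03%, 59.2%, 35.8%, 30.9%, 23.4%, 25.7% and 37.0% in that order, and 26.1% for merged clusters. The share of ESC control loops in NPC control was 74.3% within 1 bin, 82.3% within 2 bins, 53.5% with FitHiChIP, 53.3% outside the crowded windows, 53.5% for pairs in both callers, 41.7% at equal length and 46.8% for merged clusters. The ratio of list lengths held its direction in all alternatives, and at an FDR under 1e-06 was 0.325 in ESCs and 0.311 in NPCs. The median distance differed by 130 kb (ESCs) and 80 kb (NPCs) with FitHiChIP, and by 40 kb (ESCs) and 80 kb (NPC control against ESC control) outside the crowded windows.

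The difference in promoter bins at both anchors was 1.80 points (ESCs), 8.59 (NPCs) and 2.29 (control lists, sign turned) with FitHiChIP, 7.35, 7.78 and -2.05 with neighbouring bins, 5.61, 4.29 and -1.14 with all annotated genes, and 9.80, 7.51 and -7.24 with the authors' peak bins. The share of promoter bins with a change below 0, which depends on the pseudocount and is not read as a loss relative to the list, was 33.1% (ESCs), 40.7% (NPCs) and 48.6% (control lists) in MAPS. It was 38.3%, 37.6% and 44.5% with FitHiChIP, 17.6%, 24.5% and 58.4% with a pseudocount of 5, 38.3% (ESCs) and 54.0% (control lists) with neighbouring bins, 39.6% (ESCs) and 38.3% (control lists) at equal length, and 45.4% (control lists) without ambiguous ends. Of the signs that turned with FitHiChIP, 3 belong to values whose interval excludes 0: Ppia in ESCs (-0.44), Gsc in NPCs (0.85) and Foxd3 between control lists (-0.0083).

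Gene lists outside the central range numbered 0 with FitHiChIP in ESCs. In NPCs they were 2 with FitHiChIP, 2 with neighbouring bins, 0 among genes with at least 5 loops and 2 as a mean, and between control lists 4 with neighbouring bins. The percentile of the clustered protocadherins was 73.2 (FitHiChIP) in ESCs, and 0.345 (FitHiChIP), 0.015 (neighbouring bins) and 0.00 (mean) in NPCs. That of the retinoic acid response genes in ESCs was 6.24 (FitHiChIP) and 15.8 (neighbouring bins), and of the housekeeping genes 99.1 (neighbouring bins) and 99.9 (mean). The neural progenitor genes lay at 3.14 (FitHiChIP) and 4.68 (at least 5 loops) in NPCs, and at 99.3 (neighbouring bins) and 97.9 (mean) between control lists. Hox genes lay at 0.58 (FitHiChIP) in NPCs and at 98.9 (FitHiChIP) and 99.8 (neighbouring bins) between control lists, and pluripotency genes there at 99.6 (at least 5 loops).

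Within 1 bin the callers shared 53.8%, 49.2%, 57.6% and 47.2% of MAPS loops and 55.9%, 39.4%, 66.5% and 48.8% of FitHiChIP loops. Log2 ratios of contact counts between the lists at shared pairs from 500 kb, scaled by the total count over called loops, were 1.00, 0.97 (sign turned, from a value whose interval holds 0) and -0.22 (sign turned), and scaled by total contacts -0.10 (sign turned), -0.28 and 0.23. Each such scaling shifts all pairs by 1 constant, so these values and their signs follow from it, and the difference of these pairs from all shared pairs stays as reported. The gap between H3K4me3 classes in ESCs was -7.87 points with FitHiChIP (sign turned), 9.70 outside the crowded windows and 9.29 within classes of FDR and distance. In NPCs it was 16.7, 25.4 and 10.9 in that order, 13.4 within 1 bin and 13.6 at equal length. All MAPS lists start at 12 contacts whatever the total, so weaker contacts are not seen in them.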

Other observations

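Both tests in this part were chosen before their values were computed, and the genes of the next paragraph were picked after their values had been seen.

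Sox2, a transcription factor of pluripotent and neural progenitor cells, held 11 MAPS loops in ESC control and 10 in ESC auxin, and 54 in NPC control and 43 in NPC auxin (chromosome 3, 34650001 to 34660000). Sox1, an early marker of neural plate, held 20, 11, 35 and 16 in the same order of lists, and Sox11 0, 0, 47 and 14. Bmp2, a BMP ligand, held 1, 0, 48 and 17, Meis1, a homeobox gene of the TALE class, 5, 3, 47 and 25, and Pou3f3, a POU domain factor of the brain, 2, 1, 29 and 8. Loops at Sox2 with auxin thus numbered 43 where Pou3f3 held 8, while unscaled reads at the bin were 10604 in NPC control and 9857 in NPC auxin for Sox2 and 10700 and 11783 for Pou3f3.

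Of 1591 promoter bins with at least 10 MAPS loops in each cell type, 0 had fewer loops after auxin in one cell type and more in the other with 95% intervals that exclude equal numbers in both and the same signs in FitHiChIP. Without these conditions, 245 bins went opposite ways in the MAPS lists, 1088 had fewer loops in both cell types, 106 more in both and 152 equal numbers in at least 1 cell type.

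The first hypothesis was that loops acquired in differentiation are lost after auxin more often than loops held in both control lists. In NPCs 40.0% of loops held in both control lists were called again after auxin and 20.2% of those in NPC control only, and in ESCs the same shares were 32.0% and 13.6%. Within classes the gap was 9.33 points in NPCs and 10.5 in ESCs, so loops found in 1 control list were called again less often in either cell type. Loops held in both control lists were chosen for having passed the thresholds in both. The gap in each cell type can follow in part from that choice and does not show a dependence on CTCF. The gap in NPCs minus that in ESCs was -1.16 (SE 0.497), so the gap was not larger for loops acquired in differentiation than for loops found in ESC control only. This SE treats the gaps as independent, although both rest on the same 28547 loops held in both control lists.

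The second hypothesis was that the same loops are lost after auxin in both cell types. Here the classes were 5 of FDR in each control list and 4 of distance. Of 28547 loops held in both control lists, 5954 were called after auxin in both cell types, against 4250.4 from independent calls within classes, a ratio of 1.40 (1.28 to 1.54 over chromosomes). Loops that share their dependence on CTCF between ESCs and NPCs could give such a ratio, but call strength within the classes could raise it as well. So could H3K4me3 peak bins at 1 or both anchors, which these classes leave out.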
